A study of Mus musculus with 22 samples.

How the data were processed

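Whole eyes of mice were profiled on Affymetrix expression arrays at 5 ages, 3 embryonic (E10.5, E12.5 and E16.5, counted in days of embryonic development) and 2 postnatal (P8 and P60, counted in days after birth). The series holds 22 arrays, 11 of mice labelled wild type and 11 of mice labelled Vax2-/-, a knockout of the homeobox gene Vax2. There were 3 arrays of each genotype at E10.5 and 2 of each at every later age. Per the labels' protocols, total RNA was isolated with TRIzol and labelled with biotin by the manufacturer's standard protocol. The labels do not say whether replicate arrays came from separate animals, litters or pools, so the p-values measure the spread between these samples, which may be technical.

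The deposited log2 values are the authors' output of RMA (robust multi-array average, which corrects the background, normalizes the arrays and summarizes the probes of a probe set), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here, and neither is the part of the Vax2 gene that was deleted. That the values are on a log2 scale was read from their range. The sorted values of arrays of the same age lay close together, with a median absolute difference of at most 0.0607, while the array medians differed between ages (8.93 at E10.5, 5.31 at E12.5, 9.10 at E16.5, 7.18 at P8 and 7.52 at P60). The values were therefore treated as normalized within each age, and no level was compared between ages. The 4 planned comparisons of wild-type eyes between successive ages were to be run only on values normalized together, and were not run. Differences between genotypes were formed within an age, but their scale can still depend on how the arrays of that age were processed.

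Of 22690 probe sets, 64 array controls were left out and 22626 were tested, with no filter on dim probe sets. The platform annotation gave 1 gene symbol for 20380 of these, several for 691 and none for 1555. Symbols were updated through the gene identifier with a RefSeq table of the assembly GRCm38.p6, to which 20351 identifiers matched. That table was used only for names and for the order of genes along chromosomes, and no coordinates are given because the array files name no genome build. The named probe sets covered 12393 genes. Genes of the fixed panel of named genes that had no probe set with a single symbol (Cyp26b1, Cyp26c1, Ephb2 and Pax2) were not analysed here. Gene lists were also tested on their measured members only, such as 21 of 29 lens genes.

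The test was limma (version 3.58.1 in R 4.3.3): 1 mean for each of the 10 groups was fitted to the 22 arrays (12 residual degrees of freedom), and contrasts were tested with lmFit, contrasts.fit and eBayes at default settings. All groups shared 1 estimate of the spread per probe set, because 2 arrays against 2 leave few degrees of freedom. The contrasts were Vax2-/- minus wild type at each age, the mean of these 5 differences, and a moderated F test of whether the difference varied between ages. P-values were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, and 0.05 was the threshold. Errors of log2 differences are standard errors of this fit. Gene lists were tested with limma's camera (preset correlation between genes of 0.01, two-sided) on the brightest probe set of each gene. The 29 lists were fixed before the data were examined and cover patterning of the eye, retinal cell types, other tissues that a whole eye carries, stress and the surroundings of Vax2. P-values of the lists were adjusted over 174 tests, 29 lists in 6 contrasts. Adjustment over a list alone refers to the probe set test of its members.

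Genes were named by a rule set before the data were examined. It takes Vax2 at every age, and up to 10 genes with the largest rise and 10 with the largest fall at each age among those past the threshold whose genotypes do not overlap. With fewer than 5 such genes, it takes the 5 lowest unadjusted p-values in each direction, as values that did not pass. For the mean effect it asks for the same sign at all 5 ages, and for the difference between ages it takes the 10 lowest p-values. Up to 4 members with the lowest p are taken from each list described, and a fixed panel of patterning, retinoic acid and opsin genes is given whatever its p. The probe set with the lowest p stands for a gene among the genes that passed.

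The alternatives were a fit of each age alone, a trended and robust variance estimate, the replicate number as a block, probe sets above the median brightness only, quantile normalization of all arrays together, 1 probe set per gene, leaving out each array in turn and, for lists, an estimated correlation between genes or the mean over the probe sets of a gene. After the data had been seen, array weights estimated per age and a fit without E12.5 were added, because the median residual standard deviation was 0.139 at E12.5 and between 0.0721 and 0.117 at the other ages. With 1 array left out of a pair, the lone array was assumed to vary like the other groups.

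The scripts were tested on simulated arrays with the real means and the real spread of each age, in which, of 22626 probe sets, 67 were changed by a log2 difference of 0.5, 67 by 1 and 66 by 2. A log2 difference of 1 was recovered in 95.5% of cases at E10.5, 89.6% at E12.5, 92.5% at E16.5, 92.5% at P8 and 88.1% at P60. Of a difference of 0.5, the share recovered was 52.2% at E10.5, 43.3% at E12.5, 47.8% at E16.5, 50.7% at P8, 38.8% at P60 and 97.0% in the mean effect. At E12.5, 64 of the 219 calls in that simulation were probe sets that had not been changed, against 9 of 172 at E10.5, 5 of 165 at E16.5, 6 of 168 at P8 and 3 of 154 at P60. Calls at E12.5 therefore carry more false positives than the threshold states. For arrays, the number of arrays limits the precision. The lowest correlation between arrays of the same age was 0.991, no arrays held identical values, and none of the 64 control probe sets passed the threshold in any contrast.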

Results

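Gene expression was measured in whole eyes of mice labelled wild type and of mice labelled Vax2-/-, a knockout of a homeobox transcription factor of the ventral eye, at 5 ages from E10.5 to P60. The series holds 22 arrays, 3 of each genotype at E10.5 and 2 of each at E12.5, E16.5, P8 and P60. Each comparison asks which genes differed between the genotypes at an age, and 2 further tests ask which differed on average over the ages and which differed by different amounts between ages. All differences are log2 values of Vax2-/- minus wild type, with the standard error of the limma fit and Benjamini-Hochberg adjusted p-values.

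The probe set for Vax2 was examined before the other genes, since it checks the genotype labels. At E10.5 it was higher in the arrays labelled Vax2-/-, with a mean of 7.96 ± 0.09 (SD, n = 3) against 6.12 ± 0.32 (SD, n = 3) in wild type, a log2 difference of 1.84 ± 0.14 (adjusted p = 3.0e-05). It was also higher at E16.5 (0.29 ± 0.17, adjusted p = 1), at P8 (0.58 ± 0.17, adjusted p = 1) and at P60 (1.15 ± 0.17, adjusted p = 0.0587), where the test did not pass. At E12.5 it was lower, at -0.71 ± 0.17, and did not pass either (adjusted p = 0.108). The signal of the targeted gene thus went against the labels at 4 of 5 ages. Its wild-type values at E10.5 lay between percentiles 23 and 28 of their arrays, so the size of that difference rests on a dim signal. The sources used here do not say which part of the gene was deleted, and a probe set outside that part checks nothing. The arrays are for this reason named by their label throughout, and every direction given for the genotype rests on it. When E10.5 was fitted alone the difference at that age no longer passed (adjusted p = 0.294).

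**Figure D1:**
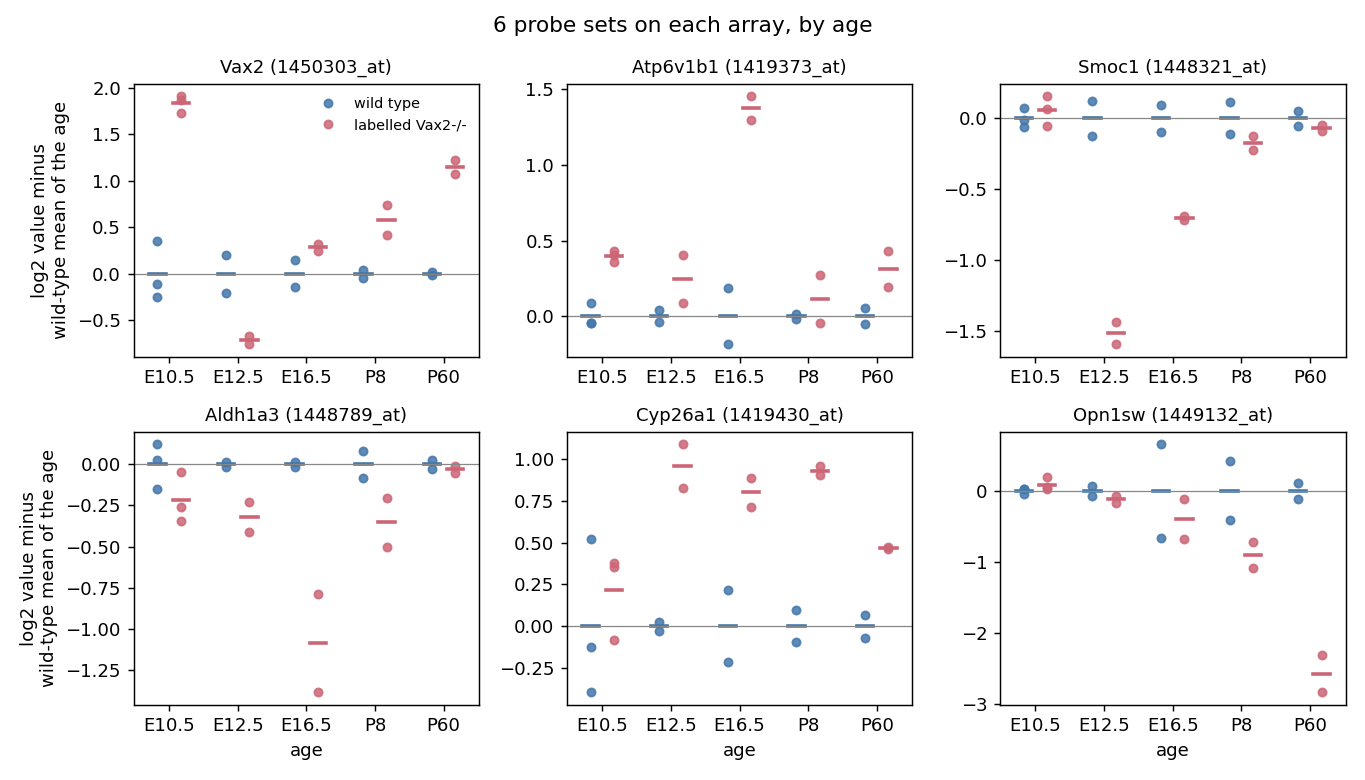
Log2 values of 6 probe sets on each of the 22 arrays, minus the wild-type mean of the same age, against age. Points are arrays, short lines are group means, blue is wild type and red is labelled Vax2-/-. Vax2 lies 1.84 above wild type at E10.5, Atp6v1b1 1.37 above it at E16.5, and Smoc1 at -1.51 at E12.5, Aldh1a3 at -1.09 at E16.5 and Opn1sw at -2.57 at P60.

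At E10.5, Vax2 was the 1 probe set of 22626 that passed. Values that did not pass included Slc1a1, a glutamate transporter, at 0.66 ± 0.11 (adjusted p = 0.396), Trib3 at 0.59 ± 0.12 (adjusted p = 0.561), Uchl4 at 0.48 ± 0.09 and Calcb, a calcitonin-related peptide, at 0.44 ± 0.09. Those on the other side were Gem, a small GTPase, at -0.57 ± 0.11 (adjusted p = 0.561), Myh6, a heart myosin, at -0.53 ± 0.12, and Lpp at -0.31 ± 0.08. The genes of retinoic acid metabolism in the fixed panel differed little at this age, with 0.22 ± 0.19 for Cyp26a1, which degrades retinoic acid, and -0.22 ± 0.13 for Aldh1a3, which makes it in the ventral retina. None of the 29 gene lists passed. An unadjusted p under 0.05 was reached by 813 probe sets, where 1131 would be expected with no effect. With Vax2-/- replicate 1 or 3 left out 2 probe sets passed. Without Vax2-/- replicate 2 there was 1 list past the threshold, and without any other array of this age there were 2.

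At E12.5, 24 probe sets rose and 13 fell, of 35 genes. An unadjusted p under 0.05 was reached by 2307, where 1131 would be expected with no effect. The largest fall was that of Smoc1, a secreted calcium-binding matrix protein, at -1.51 ± 0.11 (adjusted p = 6.7e-06), from 6.48 ± 0.17 (SD, n = 2) in wild type to 4.96 ± 0.11 (SD, n = 2). Further falls were those of Fmn2, a formin that nucleates actin, at -0.91 ± 0.11, Ganc, an alpha-glucosidase, at -0.79 ± 0.09, the netrin receptor Unc5c at -0.77 ± 0.11, Rad51ap1, a protein of recombination repair, at -0.71 ± 0.11, Stfa3 at -0.70 ± 0.11 and Pld4 at -0.64 ± 0.09. Arsg was lower at -0.59 ± 0.11, Tepsin at -0.56 ± 0.10 and Lhx2, a LIM homeobox factor of eye development, at -0.55 ± 0.09, and these 3 falls passed as well. The largest rises were those of Pla2g7, an enzyme that inactivates platelet-activating factor, at 1.42 ± 0.25, the calcineurin regulator Rcan2 at 1.32 ± 0.18, skeletal actin Acta1 at 1.21 ± 0.21 and the transcription factor Ebf2 at 1.11 ± 0.19. Abhd12 rose by 0.96 ± 0.14, Niban1 by 0.91 ± 0.13, Clstn2 by 0.90 ± 0.16, Rasl2-9 by 0.88 ± 0.12, the noncoding RNA Meg3 by 0.71 ± 0.11 and the lysophosphatidic acid receptor Lpar4 by 0.68 ± 0.12. In each of these genes both arrays labelled Vax2-/- lay on the same side of both wild-type arrays, which the rule for naming requires and which adds no support. Some of these signals were dim: both means of Stfa3 (2.09 and 2.79) and the wild-type means of Rasl2-9 (2.50) and Clstn2 (2.58) lay below the lower quartile of each array of this age, which was 2.86 at the lowest. Adjusted p-values of the named genes other than Smoc1 lay between 0.0042 and 0.0397. The other probe sets for Meg3 were smaller in difference, between 0.21 and 0.35. Cyp26a1 at 0.96 ± 0.23 (adjusted p = 0.0992) did not pass, and neither did Aldh1a3. Its probe set described at the other ages was at -0.32 ± 0.16 (adjusted p = 0.527), and its others at -0.67 ± 0.17 (adjusted p = 0.117) and -0.34 ± 0.20.

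The E12.5 count depended on the spread shared between ages. The median residual standard deviation was 0.139 at E12.5, 0.0853 at E16.5 and 0.0721 at P60, so counts of different ages cannot be compared directly. With array weights estimated per age 1 probe set passed, that of Smoc1, with the age fitted alone 0 did, and with a trended and robust variance 24 did, which lost Lpar4, Arsg and Tepsin. With all arrays quantile normalized together, 503 rose and 506 fell, against 24 and 13 on the deposited scale. Leaving out any of the 4 arrays gave more calls: 187 without wild-type replicate 1, 231 without wild-type replicate 2, 115 without Vax2-/- replicate 1 and 242 without Vax2-/- replicate 2. Some named genes were lost in these fits all the same. Without wild-type replicate 1 these were Clstn2 and Lhx2, without wild-type replicate 2 Pla2g7, Acta1, Lpar4, Arsg and Tepsin, without Vax2-/- replicate 1 Pla2g7, Acta1, Ebf2, Lpar4 and Tepsin, and without Vax2-/- replicate 2 Meg3, Arsg and Lhx2. The highest adjusted p among them was 0.103, that of Pla2g7. Vax2 passed at this age without wild-type replicate 1, at -0.92 (adjusted p = 0.0475).

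Of the gene lists, 4 passed at E12.5. Skeletal muscle genes rose (adjusted p = 2.8e-07, and adjusted p = 0.642 with an estimated correlation), with 21 of 27 members higher. Of these 1 passed over all probe sets, Acta1, and 15 rose when adjusted over the list alone, among them Myl1 at 1.72 ± 0.38, Tnnt1 at 1.15 ± 0.29 and Myh3 at 1.16 ± 0.29. The mean of this list differed by more between the wild-type arrays, at 0.38 and -0.38 around their mean, than between genotypes, with 0.65 and 0.53 in the arrays labelled Vax2-/-. Dorsal eye genes rose (adjusted p = 0.0025, and adjusted p = 0.136 with an estimated correlation), with all 10 measured members higher in their brightest probe set. Of these, 0 passed the threshold over all probe sets and 2 did adjusted over the list alone, Tbx3 at 0.50 ± 0.13 and Bambi, a BMP pseudoreceptor, at 0.36 ± 0.10. Other probe sets of Efnb2, a member of this list, lay at -0.31 to 0.022 and at -0.22 to 0.13 with 1 array left out. Retinal progenitor genes fell (adjusted p = 6.7e-04, and adjusted p = 0.642 with an estimated correlation), with 15 of 16 lower. Lhx2 passed over all probe sets and adjusted over the list alone, while Dll1 had -0.42 ± 0.14 and Hes5 -0.46 ± 0.24. Retinal ganglion cell markers fell (adjusted p = 0.0059, and adjusted p = 0.781 with an estimated correlation), with 15 of 18 lower, 0 past the threshold over all probe sets and 1 adjusted over the list alone, Tubb3 at -0.45 ± 0.13. The mean of the ganglion cell list was -0.19, and 0.0080 without Vax2-/- replicate 2. Without wild-type replicate 2 the muscle, ganglion cell and progenitor lists were lost, without Vax2-/- replicate 2 the dorsal, ganglion cell and progenitor lists, and without wild-type replicate 1 the dorsal list. Their highest adjusted p-values were 0.137 for muscle, 0.148 for dorsal, 0.990 for ganglion cell and 0.808 for progenitor genes.

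At E16.5, Atp6v1b1, which encodes a subunit of the vacuolar proton pump and is the gene next to Vax2 on chromosome 6, rose by 1.37 ± 0.13 (adjusted p = 7.2e-04) and was the 1 probe set that passed. Aldh1a3 at -1.09 ± 0.16 (wild type 11.03 ± 0.02, Vax2-/- 9.94 ± 0.42, SD, n = 2) and Smoc1 at -0.70 ± 0.11 came close to the threshold, each with adjusted p = 0.0528. The other probe sets for Aldh1a3 were also lower, at -0.95 ± 0.17 and -0.71 ± 0.20. Cyp26a1 was at 0.80 ± 0.23 (adjusted p = 1). Among values further from the threshold were Timm8a2 at 0.74 ± 0.14, Slc35f4 at 0.48 ± 0.09, Pla2g2c at 0.47 ± 0.09, Cenpe at -0.48 ± 0.10 and the dopamine receptor Drd2 at -0.61 ± 0.14. The 4 measured sex-linked genes had a median difference of 2.60 at this age. A share of the E16.5 differences that goes with the sex of the animals therefore stays open and was not tested. At an unadjusted p under 0.05 there were 620 probe sets, below the 1131 expected with no effect. The shared spread makes this test cautious as well, as the median residual standard deviation was 0.0853 at E16.5 and 0.139 at E12.5. The count was 0 with the age fitted alone and 2 without dim probe sets, a filter that removed Atp6v1b1. It rose to 3 with a trended and robust variance, with 1 probe set per gene and with array weights per age, to 7 without wild-type replicate 1 and to 4 without Vax2-/- replicate 2. Aldh1a3 passed without Vax2-/- replicate 2 (adjusted p = 0.0038) and had up to 0.321 without another array.

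At E16.5, dorsal eye genes rose (adjusted p = 2.5e-06), and this list held with an estimated correlation (adjusted p = 0.0210). Of its 10 members 9 were higher, none passed over all probe sets, and 1 rose adjusted over the list alone, Bambi at 0.41 ± 0.10. Tbx3 was at 0.38 ± 0.13, Tbx2 at 0.30 ± 0.14 and Tbx5 at 0.27 ± 0.14. Another probe set of Tbx5 lay at -0.088 to 0.18 with 1 array left out. Ventral eye and optic stalk genes fell (adjusted p = 0.0253), a call lost with an estimated correlation (adjusted p = 0.625). Their mean was -0.20 and their median -0.02, with 4 of 8 lower, and Aldh1a3 was the 1 member that passed adjusted over the list alone, ahead of the BMP receptor Bmpr1b at -0.57 ± 0.22. Without wild-type replicate 1, wild-type replicate 2 or Vax2-/- replicate 1 the ventral list did not pass, with adjusted p-values up to 0.197. The lists that passed numbered 4 without wild-type replicate 1, 4 without Vax2-/- replicate 1 and 6 without Vax2-/- replicate 2.

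**Figure D2:**
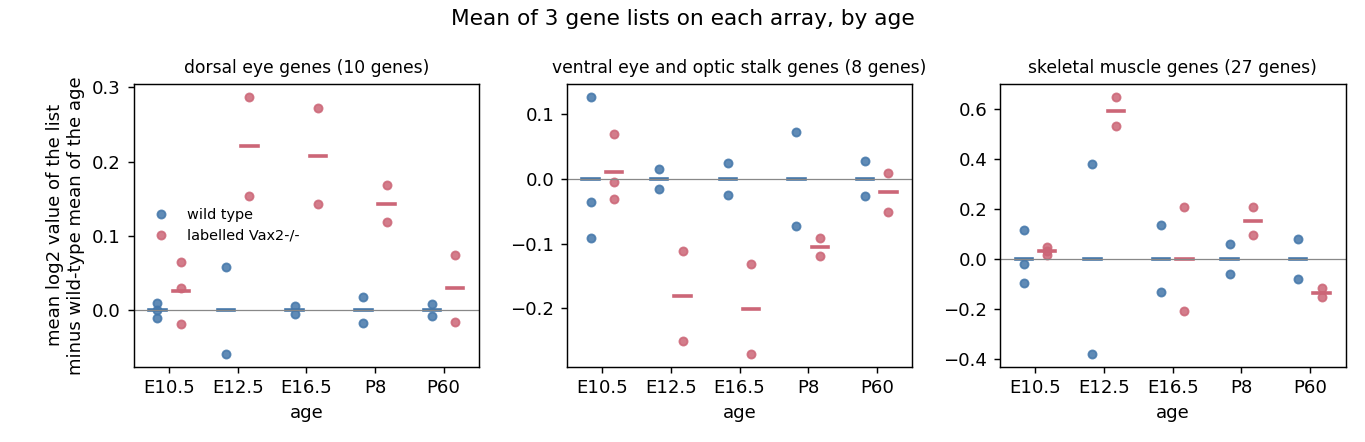
Mean log2 value of 3 gene lists on each array, minus the wild-type mean of the same age, against age. Points are arrays, short lines are group means, blue is wild type and red is labelled Vax2-/-. The dorsal list (10 genes) lies above wild type by 0.22 at E12.5, 0.21 at E16.5 and 0.14 at P8, and the muscle list (27 genes) separates the wild-type arrays of E12.5 as well.

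At P8, limma called 0 probe sets, and 719 had an unadjusted p under 0.05, below the 1131 expected with no effect. With all its arrays the age gave 0 in every other setting as well, but 140 probe sets passed without wild-type replicate 2, 133 without Vax2-/- replicate 1 and 2 without Vax2-/- replicate 2. Values that did not pass included Cyp26a1 at 0.93 ± 0.23, Fabp7, a fatty acid binding protein of glia and progenitors, at 0.55 ± 0.12, Cd24a at 0.34 ± 0.08 and Drd4 at -0.44 ± 0.10. The short-wavelength cone opsin Opn1sw was at -0.91 ± 0.33 and -0.79 ± 0.29 in its pair of probe sets, and the middle-wavelength opsin Opn1mw at -0.46 ± 0.13, each with adjusted p = 1. The first of these Opn1sw values was -0.49 without wild-type replicate 2.

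Of the lists, 9 passed at P8, and none of them held with an estimated correlation. Dorsal eye genes rose (adjusted p = 6.7e-04, and 0.108 with an estimated correlation), with 7 of 10 higher, led by Bambi at 0.31 ± 0.10 and Efnb2, an ephrin of the dorsal retina, at 0.28 ± 0.09, the 2 members that rose adjusted over the list alone. Photoreceptor transcription factors rose (adjusted p = 0.0059, and 0.638 with an estimated correlation), with 10 of 10 higher, as did lens genes with 21 of 21 higher (0.0025, and 0.625 with an estimated correlation) and muscle genes with 24 of 27 higher (0.0080, and 0.866). Thrb was at 0.52 ± 0.23, the lens channel Mip at 0.49 ± 0.17 and Myh4 at 0.41 ± 0.18. Mesenchyme and connective tissue genes fell (adjusted p = 2.2e-06, and 0.642 with an estimated correlation), with 15 of 18 lower and Col5a1 at -0.33 ± 0.10. Endothelial markers fell with 13 of 15 lower (0.0013, and 0.642 with an estimated correlation), bipolar cell markers with 12 of 13 lower (0.0059, and 0.136), Mueller glia markers with 12 of 13 lower (0.0374, and 0.642) and cornea and conjunctiva genes with 15 of 18 lower (0.0207, and 0.638). No member of these 8 lists passed over all probe sets or adjusted over its list alone. Without dim probe sets 4 lists passed at this age, without wild-type replicate 2 it was 5 and without Vax2-/- replicate 1 it was 4. Bipolar, Mueller glia, cornea and muscle lists were lost without either of these arrays, and mesenchyme and endothelial lists without Vax2-/- replicate 1. Photoreceptor and lens lists were lost without wild-type replicate 1 or Vax2-/- replicate 2, and the mesenchyme list without wild-type replicate 1 as well. Over these fits, adjusted p-values reached 0.948 for Mueller glia, 0.634 for lens and 0.122 for mesenchyme genes. In wild-type replicate 1 the log2 signal of the 3' minus the 5' control probe sets, a sign of RNA quality, was 0.158 for Gapdh and 0.711 for Actb, against -0.0202 to -0.0011 and 0.456 to 0.532 in the other arrays of P8.

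At P60, Opn1sw fell by 2.57 on the log2 scale, with a standard error of 0.33 (adjusted p = 0.0150), from 11.65 ± 0.15 (SD, n = 2) to 9.08 ± 0.37 (SD, n = 2). Its other probe set was at -1.71 ± 0.29 and did not pass (adjusted p = 0.132). Meg3 rose by 0.82 ± 0.11 (adjusted p = 0.0150), from 8.75 ± 0.22 to 9.57 ± 0.05, in another probe set than the one called at E12.5. The probe set called at E12.5 was at 0.19 ± 0.11 at P60, and that called at P60 was at 0.21 ± 0.11 at E12.5. Opn1mw was at 0.61 ± 0.13 (adjusted p = 0.574), histidine decarboxylase Hdc at 0.52 ± 0.10, complement factor Cfi at 0.92 ± 0.19, Lmo2 at 0.43 ± 0.09, Tax1bp1 at -0.70 ± 0.13 and Ppp1cb at -0.52 ± 0.12. At an unadjusted p under 0.05 there were 389 probe sets, below the 1131 expected with no effect. The spread shared between ages makes the test cautious here, since the median residual standard deviation was 0.0721 at P60 and 0.139 at E12.5. A count below 1131 therefore does not show that effects are absent. The call of Opn1sw was lost when any of the 4 arrays was left out, with adjusted p between 0.0615 and 0.136, and that of Meg3 was lost without wild-type replicate 2 or either Vax2-/- array, with adjusted p up to 0.219. With wild-type replicate 1 left out 4 probe sets passed, with wild-type replicate 2 left out 0 did, and with either Vax2-/- array left out 1 did. Neither gene passed with the age fitted alone (adjusted p = 0.416 for Opn1sw and 0.948 for Meg3). Without dim probe sets 1 probe set passed, and that filter had removed the called probe set of at least 1 of these genes. With array weights per age 11 probe sets passed, and with a trended and robust variance 6 did.

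At P60, 3 lists fell, and none held with an estimated correlation. Retinal pigment epithelium and pigmentation genes had 15 of 16 members lower (adjusted p = 3.4e-05, and 0.487 with an estimated correlation), with Slc45a2 at -0.32 ± 0.13 and Pmel at -0.28 ± 0.14. Muscle genes had 25 of 27 lower (0.0270, and 0.953 with an estimated correlation), and mesenchyme and connective tissue genes had 16 of 18 lower (0.0171, and 0.866), with Lum at -0.31 ± 0.16. No member passed over all probe sets or adjusted over its list alone. Each of the 3 lists was lost without wild-type replicate 2 and without Vax2-/- replicate 2, where 1 list not among them passed in each fit. The 3' minus 5' signal of Actb was 1.18 in wild-type replicate 2, against 0.975 to 1.01 in the other arrays of P60. Without wild-type replicate 1 or Vax2-/- replicate 1, 5 lists passed.

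Averaged over the 5 ages, 3 probe sets rose and 1 fell. Cyp26a1 rose by 0.68 ± 0.10 (adjusted p = 0.0304) and Atp6v1b1 by 0.49 ± 0.06 (adjusted p = 0.0035), each higher at all 5 ages. Vax2 rose by 0.63 ± 0.08 (adjusted p = 0.0035) and Smoc1 fell by 0.48 on the log2 scale, with a standard error of 0.05 (adjusted p = 4.8e-04). These had the same sign at 4 ages and are named by other parts of the rule. Aldh1a3 was lower at all 5 ages, at -0.40 ± 0.07 (adjusted p = 0.137). Opn1sw was at -0.78 ± 0.14 (adjusted p = 0.179), Opn1mw at 0.06 ± 0.06, Efnb2 at 0.12 ± 0.04, Tbx5 at 0.16 ± 0.06, Bmp4 at 0.05 ± 0.09, Vax1 at -0.01 ± 0.05 and Aldh1a1 at 0.04 ± 0.06. Without E12.5, 2 probe sets passed, and Smoc1 and Cyp26a1 were not among them (adjusted p = 0.460 for each). With all arrays quantile normalized together 7 rose and 7 fell, against 3 and 1. Without dim probe sets 2 passed, as that filter removed Vax2 and Atp6v1b1. The count was 42 without P8 Vax2-/- replicate 1 and 9 without P8 wild-type replicate 2. Cyp26a1 passed in 5 of the 22 fits that left out an array.

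Of the lists, 4 passed in the mean effect. Dorsal eye genes rose (adjusted p = 1.4e-07), with all 10 members higher, and held with an estimated correlation (adjusted p = 0.0140). None passed over all probe sets, and 5 rose adjusted over the list alone, led by Bambi at 0.22 ± 0.04, Tbx3 at 0.24 ± 0.06, Efnb2 at 0.12 ± 0.04 and Tbx2 at 0.18 ± 0.06. Ventral eye and optic stalk genes fell (adjusted p = 0.0095, and 0.487 with an estimated correlation), with 7 of 8 lower and 1 past the threshold adjusted over the list alone, Aldh1a3. Muscle genes rose with 23 of 27 higher (6.7e-04, and 0.826 with an estimated correlation), and mesenchyme and connective tissue genes fell with 15 of 18 lower (0.0025, and 0.847). The list of genes of retinoic acid metabolism and signalling did not pass, with 9 of 21 members higher and adjusted p = 0.952. Its test and median pointed down and its mean, at 0.01, up. Of the 4 lists 2 passed without E12.5. Without E12.5 wild-type replicate 2 it was 2 lists in all, and without P60 Vax2-/- replicate 1 it was 8. The ventral list was lost without E12.5 wild-type replicate 2 or Vax2-/- replicate 1 (adjusted p up to 0.0989), and the muscle list without E12.5 wild-type replicate 2 or E16.5 Vax2-/- replicate 2 (up to 0.275). The mesenchyme list was lost without P8 wild-type replicate 1, P8 Vax2-/- replicate 1, P60 wild-type replicate 2 or P60 Vax2-/- replicate 2 (up to 0.0844).

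The difference between the genotypes varied between ages for 2 probe sets. That of Smoc1 was 0.05 at E10.5, -1.51 at E12.5, -0.70 at E16.5, -0.18 at P8 and -0.07 at P60 (adjusted p = 0.0014 for the F test). That of Vax2 was 1.84, -0.71, 0.29, 0.58 and 1.15 at the same ages (adjusted p = 0.0017). Atp6v1b1, Ganc, Pld4, Bbx and Fmn2 followed with adjusted p = 0.198 each, so the larger value of Atp6v1b1 at E16.5 was not shown to differ from those at other ages. Niban1, Unc5c and Rcan2 had 0.215, 0.257 and 0.407. Without E12.5, 0 probe sets passed this test, without dim probe sets, where Vax2 was not tested, 1 did, and with quantile normalization 141 did. It was 14 without E12.5 wild-type replicate 1, 5 without E12.5 Vax2-/- replicate 1, 5 without P8 wild-type replicate 2 and 70 without P8 Vax2-/- replicate 1. When the arrays within each age were split into 2 sets, 73 of 100 splits, the real one among them, gave at least 2 probe sets. Chance is therefore not excluded for this count. The values were treated as normalized within each age, and the size of a difference may depend on that processing.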

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

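The differences in the Smoc1 and Vax2 effects between ages were tested by a planned F test. The comparison with neighbouring genes was chosen after the result had been seen, and the tests on held-out ages before.

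The difference between genotypes varied with age for Smoc1 (adjusted p = 0.0014) and for Vax2 (adjusted p = 0.0017). In Smoc1 it was near 0 at E10.5 and at its lowest at E12.5, -1.51 ± 0.11. Of 100 splits of the arrays within ages, 73 gave at least as many probe sets as the 2 found here, the highest other count being 243, so chance cannot be excluded for the count. Splits with counts that high may point to a structure of the samples, which was not tested. Without E12.5 no probe set passed.

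The Vax2 probe set was brighter in the arrays labelled Vax2-/- at 4 ages, by 1.84 at E10.5, and dimmer at E12.5. An exchange of the genotype labels at E10.5 was tested with 20 probe sets chosen by their mean effect over the other 4 ages, away from the surroundings of Vax2. Of these, 13 kept their direction at E10.5, and the mean signed log2 difference was 0.0658, above 98.7% of 10000 random sets. This argues only weakly against an exchange at that age alone. Random sets allow for neither variation between arrays nor joint regulation of the chosen probe sets. The same test gave 0.0763 at P60, above 99.6% of random sets and with 13 of 20 in the same direction, and 0.223 at E12.5, 0.178 at E16.5 and 0.162 at P8. It takes its directions from the labels of the other ages, so it could not detect an exchange made at every age, which stays open.

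The 20 measured genes nearest to Vax2 on chromosome 6 had a mean absolute moderated t of 1.64 in the mean effect. This was above 99.8% of all runs of neighbouring genes, whose median was 0.794. Those runs include the ones that overlap this region. Without Atp6v1b1, the called gene that prompted the test, it was 1.28, above 99.0%. The longer list of chromosome 6 genes near Vax2, fixed before the data were examined, passed in no contrast (adjusted p = 0.785 in the mean effect). That test asks for a shift in a common direction, so it cannot count against changes in both directions. In the mean effect, 4 of the 47 measured members rose and 1 fell when adjusted over the list alone. An altered chromosome segment around Vax2 may contribute and stays open, and an effect of Vax2 loss on its own transcript was not tested.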

How the results depend on the processing

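Array weights per age and a fit without E12.5 were chosen after the data had been seen, the other settings before. In 8 settings besides leaving out arrays, 172 called differences of named genes were recomputed, of which 112 still passed and 0 changed sign. With 1 array left out, 124 of 166 still passed. With an array of a pair left out, the lone array was assumed to vary like other groups. The 4 comparisons of wild-type eyes between ages were not run. The number of arrays limits the precision.

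With each age fitted alone, 0 probe sets passed at E10.5, E12.5, E16.5 and P60, and 1 gene list at E16.5. Vax2 at E10.5 was 1.84 as before and no longer passed. Such a fit has fewer samples to estimate the spread from. With a trended robust variance the count was 24 at E12.5, 3 at E16.5 and 6 at P60, and Vax2 at P60 passed at 1.15. The filter on dim probe sets removed those of Vax2, Atp6v1b1 and other called genes, so their calls were not tested with it. Besides Vax2, it left 12 called differences of named genes, against 28 with a trended robust variance, and all 12 passed. Without dim probe sets the count was 0 at E10.5, 2 at E16.5, 1 at P60 and 2 in the mean effect. It was 1 in the F test between ages, and 4 lists passed at P8. With quantile normalization of all arrays it was 1009 at E12.5, 14 in the mean effect and 141 in the F test. Vax2 passed at -0.60 at E12.5 and at 1.32 at P60, and signs changed in Efnb2 at E10.5 (-0.016), Aldh1a1 at E16.5 (0.018) and Tbx5 at P60 (-0.0055), which had not passed. With 1 probe set per gene the count was 3 at E16.5, and Vax2 at P60 passed at 1.15, as fewer probe sets were tested. With an estimated correlation, 0 lists passed at E12.5, 1 at E16.5, 0 at P8, 0 at P60 and 1 in the mean effect, and with the mean over probe sets 1 at E16.5. With array weights per age the counts were 1 at E12.5, 3 at E16.5 and 11 at P60, with Vax2 at P60 past the threshold at 1.15 and 1 list at E16.5. Without E12.5 they were 2 in the mean effect and 0 in the F test, with 2 lists in the mean effect, and signs changed in Ganc (0.014), Pld4 (0.058), Bbx (-0.064), Niban1 (-0.13), Rcan2 (-0.025) and Vax1 (0.0014). Where no cause is named, the cause was not tested.

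With the replicate number as a block, 1 probe set passed at P60 and 0 in the F test, and 1 gene list each at E10.5 and E16.5. Meg3 at P60 and Abhd12, Rasl2-9, Meg3, Rad51ap1, Stfa3 and Arsg at E12.5 did not pass in that fit. Arrays with the same number had correlated deviations of 0.23, 0.55 and -0.01 at E10.5, where not every array correlated best with its own number, and of 0.28 at E12.5, 0.18 at E16.5, 0.44 at P8 and 0.46 at P60. They were treated as sharing only a number.

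With 1 array left out, the count of probe sets was 1 to 2 at E10.5, 115 to 242 at E12.5, 1 to 7 at E16.5, 0 to 140 at P8, 0 to 4 at P60, 3 to 42 in the mean effect and 2 to 70 in the F test. The count of lists was 1 to 2 at E10.5, 1 to 5 at E12.5, 2 to 6 at E16.5, 4 to 9 at P8, 1 to 5 at P60 and 2 to 8 in the mean effect. The ganglion cell list at E12.5 was -0.38 to 0.0080, and Vax2 at E12.5 was -0.92 to -0.51.

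Of all values recomputed, 54 that had not passed changed sign, the largest being 0.375 in size. With 1 array left out, Aldh1a1 was -0.0060 to 0.12 (E10.5), -0.022 to 0.047 (E12.5), -0.089 to 0.085 (E16.5) and -0.014 to 0.086 (mean). Aldh1a3 was -0.18 to 0.019 and -0.29 to 0.067 in probe sets at E10.5, -0.090 to 0.049 (P8), and -0.22 to 0.034 and -0.22 to 0.028 (P60). Bmp4 was -0.040 to 0.11 (E10.5), -0.38 to 0.54 (E12.5), -0.13 to 0.098 (P8), -0.17 to 0.13 (P60) and -0.046 to 0.14 (mean). Efnb2 was -0.12 to 0.22 and -0.079 to 0.14 (E10.5), -0.049 to 0.16, -0.31 to 0.022 and -0.22 to 0.13 (E12.5), -0.13 to 0.13 (E16.5) and -0.14 to 0.33 (P60). Vax1 was -0.20 to 0.13 (E16.5), -0.085 to 0.049 (P8) and -0.044 to 0.022 (mean). Tbx5 was -0.088 to 0.18 (E16.5), -0.15 to 0.021 (P8), and -0.11 to 0.44 and -0.0044 to 0.0044 (P60). Opn1sw was -1.05 to 0.26 (E16.5).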

Other observations

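The splits over all ages were planned before their results were seen. The splits at E10.5, that of the lowest p of any list, and the tests on mesenchyme, ventral genes and cone genes were chosen after.

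Near Vax2, besides Atp6v1b1, the genes with an unadjusted p under 0.05 in the mean effect among the 20 nearest measured were Dysf, at 0.29 and higher at every age, and Cd207, at -0.21. In the imprinted region of Meg3, 5 probe sets for Meg3 were between 0.19 and 0.82 at P60 and between 0.21 and 0.71 at E12.5. At E12.5 the paternally expressed neighbour Dlk1 was at 0.58 ± 0.11. The noncoding RNA Rian was at 0.59 ± 0.21 in 1 of its probe sets at that age. These genes were chosen after their values were seen. The list of 4 sex-linked genes passed at no age. Its mean differed between genotypes by 1.34 at E16.5 (adjusted p = 0.392) and by -0.84 at E12.5 (adjusted p = 0.879). Its median was 2.60 at E16.5, with 3 members higher and 1 lower, and -0.03 at E12.5, with 1 higher and 3 lower. The list as fixed holds Xist and genes of the Y chromosome, which differ in opposite directions between the sexes. A test of a common shift therefore cannot decide whether the sexes were unequal. A share of the differences at E12.5 and E16.5 that goes with the sex of the animals stays open and was not tested. The correlation of the genotype differences between pairs of ages, across probe sets above the median brightness, is a correlation across genes, which are not independent replicates, and it was 0.20 at most.

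Whether chance gives results as large was counted over splits. At E10.5, 6 of the 10 splits of the 6 arrays gave at least the 1 probe set of the real one, the highest other being 3, and 10 splits are too few for a share under 0.05. In the mean effect, 29 of 100 splits within ages gave 4 or more probe sets, the highest being 31, and 50 gave 4 or more gene lists, the highest being 8. Chance can be excluded for neither count, and splits with 31 probe sets may point to a structure of the samples, which was not tested. The mean shift of the dorsal list, 0.125, was reached by 1 of 100 splits, the real one, and the highest other was 0.102. Chance is therefore unlikely for this list taken alone, as far as 100 splits can tell. This makes no allowance for its choice among 29 lists. The lowest p of any list, that of the dorsal list with a -log10 of 9.11, was matched or passed in 38 of 100 splits, the highest other being 24.2, so chance cannot be excluded for a list chosen by its p.

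The rise of dorsal eye genes at E12.5, E16.5 and P8 was set against more mesenchyme in the arrays labelled Vax2-/-, since several of these genes are also expressed there. With an estimated correlation the dorsal list held at E16.5 (adjusted p = 0.0210) and not at E12.5 (0.136) or P8 (0.108). The mesenchyme list had a mean shift of -0.0316 ± 0.0110 (SE over 18 genes) at E16.5, -0.187 ± 0.0472 at P8, 0.0278 ± 0.0273 at E12.5 and -0.0635 ± 0.0189 over the 3 ages. Its test passed at P8 alone, where it was lost with an estimated correlation (adjusted p = 0.642) and without wild-type replicate 1 or Vax2-/- replicate 1. More mesenchyme therefore stays open at each age.

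A hypothesis for the dorsal list is that the eye lost part of its ventral pattern. It asks for a fall of the ventral list, which had a mean shift of -0.162 ± 0.0729 (SE over 8 genes) over the same ages, and -0.102 ± 0.0469 without Aldh1a3. The same data raised and tested it, and the ventral list did not pass with an estimated correlation at any of these ages, so it stays open.

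The fall of Opn1sw at P60 was set against a loss of cones, which would lower other cone genes by a similar amount. The 11 other measured cone genes had a mean log2 difference of 0.0835 ± 0.0757 (SE over genes), with Arr3 at 0.42 ± 0.16, Gnat2 at 0.01 ± 0.20 and Kcne2 at -0.19 ± 0.44. Adjusted over the list alone, Opn1mw rose, at 0.61 ± 0.13, and Ccdc136 fell, at -0.26 ± 0.08. These values argue against a loss of cones of the size of the Opn1sw change. No other biological explanation was tested for Opn1sw.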
